A study of Mus musculus with 33 samples.

How the data were processed

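RNA polymerase II (Pol II) was mapped by CUT&RUN, a method in which an antibody tethers a nuclease to its target in permeabilised cells and the released DNA is sequenced. The cells were mouse natural killer (NK) cells, innate lymphocytes that kill infected cells and secrete interferon-γ. Per the labels' protocols, NK cells were enriched from spleen, expanded in IL-15 for several days, and given IL-12 at 20 ng/ml, IL-18 at a lower dose of 10, both, or medium alone. In 1 study wild-type cells were treated for 3 h. In the other studies cells were given IL-12 for 15 min, in wild-type and Stat4 knockout cells or in wild-type and Ddx5 knockout cells. STAT4 is the transcription factor activated by the IL-12 receptor, and DDX5 is a DEAD-box RNA helicase that binds several transcription regulators.

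Per the labels' protocols, yeast spike-in DNA was added at extraction, the 3 h libraries were made with a Pol II antibody from Bethyl and the 15 min libraries with clone CTD4H8. Antibody, duration and batch label therefore changed together between the 3 h table and the 15 min tables, and nothing separates them there. The 15 min tables share antibody and duration and differ in batch label. Their wild-type libraries also differ in reads on the Y chromosome. Every comparison was made inside 1 table, where antibody and batch label were constant. The series has 33 libraries. The 28 libraries with deposited values form 12 groups, with 3 libraries per group at 3 h and 2 per group at 15 min. The 5 input libraries were not used here, and no library with deposited values was left out.

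The deposited unit is signal, a normalized Pol II amount per window, in the words used here for the authors' values. Per the file headers, each value belongs to a 1001 bp window, 500 bp to either side of a transcription start, on mm10. Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.4.1, MACS2 2.2.7.1, DESeq2 1.46.0 and deepTools 3.5.2 were among the programs used, without the part each played. How the scale factors were set, whether the yeast DNA entered them, and how the start windows were picked were not given in the sources used here. Each deposited column divided exactly into whole numbers by 1 factor per library (100.0% of values in all 28 columns at a tolerance of 0.02), so whole reads were recovered and the factor of each library became visible.

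The tables hold 8917 windows at 3 h, 5364 in the Stat4 study and 8889 in the Ddx5 study. Gene identifiers were matched by name to RefSeq (GRCm38.p6), which found 8915, 5363 and 8887 of them. Overlapping windows share reads, so a change in 1 of them cannot be assigned to 1 gene. Among the genes named, Nfkb2 shares its window with 4833438C02Rik, Supt6 with Sdf2, Nlrc5 with 9330175E14Rik, Map3k8 with Gm50096, Mipol1 with Prps1l3, Pcsk7 with Rnf214, Prune1 with Mindy1, and Psmb9 with Tap1. There were 2486, 1780 and 2443 such windows, and the distinct places numbered 7659, 4464 and 7653. Positions are given 1-based and inclusive.

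The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(deposited signal + 1), two-sided, with Benjamini-Hochberg adjusted p < 0.05. Windows with a mean of at least 10 signal were tested, which left 8873, 5218 and 7916. Each table was fitted once over all its groups, without a block. The sources do not state whether replicates are separate animals, cultures or library preparations, so every p-value measures only the spread between these samples. In limma the spread of each window is drawn toward the trend over all windows of its table. An SE can therefore be smaller than the spread of the compared libraries at that window.

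The comparisons, groups, threshold and filter were fixed before the data were examined. The departure from additivity was the effect of both cytokines minus the sum of the single effects on the log2 scale. The genotype difference was the IL-12 effect in knockout minus that in wild type. Other settings fixed at the same time were a pseudocount of 10, no filter, libraries rescaled to the same total, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads with the authors' scale, a fit on the compared groups only, replicate number as block, and each library left out in turn. Added after the values were seen were edgeR with TMM factors, a refit without the 2 shallow libraries of the Ddx5 study, a refit of the Stat4 study without windows on X and Y, a rescaled refit without its highest-total library, rescaled values of the genes raised at 15 min in wild type of both studies, and settings for the cross-table and overlap results.

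Deposited totals differed between libraries. Rescaled values are printed beside many, not all, of the main values of the Stat4 study and where the choice changed the call of a gene named by the rule. The libraries held 410379 to 609891 recovered reads at 3 h, 146863 to 471765 in the Stat4 study and 145564 to 737023 in the Ddx5 study. The 2 shallow libraries of the Ddx5 study were unstimulated wild-type replicate 1 (152216 reads) and IL-12 knockout replicate 3 (145564 reads). Where a group had 3 reads or fewer, a ratio of pooled reads with a 95% counting interval is printed. Where a group had 0 reads, a bound against a floor of 3 reads per library is printed. These intervals and floors cover counting error only, since PCR copies cannot be told apart without molecular tags.

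Gene lists were typed from general knowledge before the data were examined. They were the IL-12/STAT4 response, JAK-STAT feedback, NF-kB/MyD88 response, cytokines and chemokines, immediate-early genes, interferon-stimulated genes, cytotoxic effectors, NK cell receptors, NK cell transcription factors, cell cycle, glycolysis, cytosolic ribosomal proteins, Pol II machinery, DEAD-box helicases, and T cell, B cell, myeloid, ILC2/ILC3 and erythroid markers. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted within each comparison, and again with the correlation estimated from the data. With an estimated correlation, adjusted p stayed below 0.05 in 2 of the 49 calls on the authors' scale: the IL-12/STAT4 list under both cytokines and under both cytokines against IL-18 alone. After rescaling, 29 of 49 list calls stayed below 0.05 with an estimated correlation. For IL-12 at 3 h, 6 rescaled lists passed with the preset and 2 with an estimated correlation. These numbers were 6 and 6 for IL-18, 7 and 6 for both, 6 and 6 for both against IL-12 and 5 and 5 for both against IL-18. At 15 min at most 1 rescaled list per comparison passed with an estimated correlation. Values printed with an estimated correlation are on the authors' scale unless called rescaled.

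Genes were named by rule: the 10 largest rises and falls among genes past the threshold whose library values did not overlap between the groups (5 each for differences of effects), or the 3 smallest p-values each way where none passed, plus Ifng, Ddx5 and Ddx17 throughout and up to 4 members per list. Genes named outside this rule were chosen after the values were seen. In the self-test, reads were simulated 1 time per comparison for the tested windows, from each window's mean over all libraries and the table's dispersion and library spread, without a table-wide shift. Of these windows 100 were changed 2-fold and 100 4-fold, and the simulated table was refitted with limma. The dispersion was estimated on the authors' scale, so it already held part of the library spread that was added. Recovery may therefore be understated.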

Results

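At 3 h the labels ask what IL-12 alone does to Pol II at gene starts in wild-type NK cells. Pol II at Ifng, the interferon-γ gene (gene identifier 15978, chromosome 10, 118440546 to 118441546), rose from 23.2 ± 4.41 to 102 ± 28.5 signal (mean ± SD, n = 3 each, log2 fold change 2.07 ± 0.28 SE, limma adjusted p = 3.4e-09). Bcl6, which encodes a transcriptional repressor (chromosome 16, 23988352 to 23989352), rose from 41.2 ± 8.56 to 160.1 ± 37.2 (1.92 ± 0.28). The death receptor gene Fas rose from 6.28 ± 2.36 to 25.3 ± 7.32, the interferon-inducible GTPase gene Gbp2 from 16.9 ± 1.50 to 58.9 ± 11.5, and Socs3, an inhibitor of cytokine receptor signalling, from 56.9 ± 8.23 to 195 ± 65.7 (n = 3 each). Gpr146, the survival kinase gene Pim2, Flot1, Rhoq and Cfap126 rose by log2 1.90, 1.85, 1.67, 1.62 and 1.60. Falls were not called on the authors' scale: Cd2, an adhesion receptor gene, had log2 -0.95 ± 0.32 (limma adjusted p = 0.25) and Pnpla7 and the window shared by Dnaaf2 and 9330151L19Rik -1.07 and -1.04 (limma adjusted p = 0.22 each). Rescaled values were -1.22 (limma adjusted p = 0.00031), -1.33 (0.0021) and -1.30 (0.0010), and all 3 also fell with edgeR and TMM factors (adjusted p = 0.00011, 0.0027 and 0.0025).

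Of 21 measured genes of the IL-12/STAT4 response, 6 rose with IL-12 at 3 h (10 adjusted over the list alone): Ifng, Bcl6, Socs3, Socs1 (log2 1.42), Cish (1.29) and Irf8 (1.04). The list moved up against the other windows (limma camera adjusted p = 1.6e-17, adjusted p = 0.255 with an estimated correlation). JAK-STAT feedback had 4 of 18 raised (7 adjusted over the list alone; camera adjusted p = 3.7e-05, adjusted p = 0.719 with an estimated correlation). Cytokines and chemokines had 1 of 12 raised, interferon-stimulated genes 1 of 21 and cytotoxic effectors 1 of 11, the granzyme gene Gzma (1.42), all 3 lists past the threshold upward (2, 3 and 3 adjusted over the list alone; camera adjusted p = 0.00017, 0.013 and 0.025, adjusted p = 0.719, 0.831 and 0.831 with an estimated correlation). Immediate-early genes had 0 of 27 raised (5 adjusted over the list alone) and a positive list shift (camera adjusted p = 0.0081, adjusted p = 0.883 with an estimated correlation). The 4 myeloid markers had 0 changed (0 adjusted over the list alone) and a negative list shift (camera adjusted p = 0.033, adjusted p = 0.719 with an estimated correlation), which did not pass after rescaling (camera adjusted p = 0.15).

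Under IL-12 at 3 h, 55 of 8873 tested windows rose and 0 fell (limma, 49 distinct places; 618 with unadjusted p < 0.05; edgeR called 52 and DESeq2 68). The median log2 change of all tested windows was 0.19 and became -0.06 after rescaling, with 190 raised and 110 lowered, so the raised share went from 100.0% to 63.3%. Rescaling gave 300 calls, edgeR with TMM factors 282 and a fit on the compared groups only 22. Without IL-12 replicate 1 the count was 685, without IL-12 replicate 2 it was 16, without IL-12 replicate 3 it was 33, and without unstimulated replicates 2 and 3 in turn it was 23 and 20.

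IL-18 signals through MyD88 and NF-kB, and IL-18 alone was compared with medium at 3 h. Gadd45b, a stress gene induced by NF-kB (chromosome 10, 80929573 to 80930573), rose from 71.6 ± 2.96 to 374 ± 90.1 signal (n = 3 each, log2 2.34 ± 0.27, limma adjusted p = 7.8e-14). Fas rose to 38.1 ± 13.2 (2.42 ± 0.33), and Thra, Zhx2, Slc11a1, Synj2, Bcl3, Cyba and Slc2a6 rose by 2.21, 1.92, 1.85, 1.76, 1.69, 1.65 and 1.63, with Bcl3 encoding an NF-kB cofactor and Cyba a subunit of the phagocyte oxidase. Milr1 rose by 1.72 in a window shared with Pecam1. Camk2b, a calmodulin-dependent kinase gene, fell from 179 ± 27.9 to 83.3 ± 15.4 (n = 3, log2 -1.10 ± 0.28, limma adjusted p = 0.016). With the replicate number as block Camk2b did not pass (limma adjusted p = 0.087). Ifng reached 48.4 ± 9.67 (1.03 ± 0.28, limma adjusted p = 0.047), a call that ended with edgeR (adjusted p = 0.14), DESeq2 (0.10), a limma pseudocount of 10 (0.16) and a limma fit on the compared groups only (0.051). It also ended in limma without IL-18 replicates 1, 2 and 3 in turn (adjusted p = 0.43, 0.065 and 0.16), unstimulated replicates 2 and 3 (0.49 and 0.37), IL-12 replicate 2 (0.085) and the replicates 1, 2 and 3 that received both cytokines (0.10, 0.11 and 0.10).

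The NF-kB/MyD88 list had 10 of 24 genes raised by IL-18 (14 adjusted over the list alone), among them Nfkb2 (log2 1.57) and the inhibitor gene Nfkbia (1.38). The list moved up (limma camera adjusted p = 8.0e-28, adjusted p = 0.212 with an estimated correlation). After rescaling, 6 of 16 lists passed for IL-18 with an estimated correlation, as many as with the preset one. Cytokines and chemokines had 3 of 12 raised (7 adjusted over the list alone), Ifng and the chemokine genes Ccl5 (1.28) and Ccl3 (1.18). Its limma camera test passed upward (adjusted p = 1.0e-06, adjusted p = 0.68 with an estimated correlation). Immediate-early genes had 2 of 27 raised (4 adjusted over the list alone), Myc (1.12) and the early activation marker Cd69 (1.26), and the IL-12/STAT4 list 2 of 21 (7 adjusted over the list alone), Ifng and Batf (1.20), with camera adjusted p = 6.9e-05 and 0.00019, adjusted p = 0.926 and 0.92 with an estimated correlation. JAK-STAT feedback had 1 of 18 raised (3 adjusted over the list alone), Pim2 (1.27), and cytosolic ribosomal proteins 0 of 72 (0 adjusted over the list alone), with camera adjusted p = 0.014 and 0.0034, adjusted p = 0.926 for both with an estimated correlation. The vesicle fusion gene Stx11 rose by 1.59 and the transcription factor gene Stat5a by 1.31.

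IL-18 raised 58 windows and lowered 2 (limma, 56 distinct places; edgeR and DESeq2 called 59 each). The median was 0.16 and became -0.01 after rescaling, with 202 raised and 124 lowered. Rescaling gave 326 calls and edgeR with TMM factors 341. The count was 107 without IL-12 replicate 1, 22 without IL-18 replicate 1, 29 without unstimulated replicate 2 and 27 without unstimulated replicate 3.

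The comparison of IL-12 plus IL-18 with medium at 3 h held the largest single rise of that table. Ifng rose from 23.2 ± 4.41 to 289.6 ± 77.5 signal (n = 3 each, log2 3.56 ± 0.28, limma adjusted p = 5.7e-32). Fas rose by log2 3.21, Gadd45b by 2.75 to 489.8 ± 57.7 signal, the STAT5 feedback gene Cish by 2.28, Ifi203 by 2.19, Pim2 by 2.18, Serpina3f by 2.13 and Zhx2 by 2.11. Csf2, which encodes the cytokine GM-CSF, rose from 9.15 ± 1.54 to 43.8 ± 10.2 (2.12 ± 0.35, limma adjusted p = 5.9e-07). Dmrta1, Camk2b and the ubiquitin ligase gene Rnf125 fell by log2 -1.65, -1.30 and -1.19, and Prr12, Tbc1d10c and Jakmip1 by -1.05, -1.05 and -1.04. With the replicate number as block Prr12, Tbc1d10c and Jakmip1 did not pass (limma adjusted p = 0.074, 0.065 and 0.066).

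In the IL-12/STAT4 list 15 of 21 genes rose with both cytokines (15 adjusted over the list alone; limma camera adjusted p = 8.3e-36, adjusted p = 0.037 with an estimated correlation). The NF-kB/MyD88 list had 12 of 24 raised (17 adjusted over the list alone; adjusted p = 7.1e-22, adjusted p = 0.127 with an estimated correlation). Cytokines and chemokines had 6 of 12 raised (9 adjusted over the list alone; camera adjusted p = 2.4e-17, adjusted p = 0.0967 with an estimated correlation), including Ccl3 (log2 2.01), Ccl4 (1.79) and Csf2. Immediate-early genes had 10 of 27 raised (14 adjusted over the list alone), among them Myc (1.67), Btg1 (1.39) and Jun (1.23). As a list these passed upward (limma camera adjusted p = 3.7e-10, adjusted p = 0.457 with an estimated correlation). JAK-STAT feedback had 5 of 18 raised (8 adjusted over the list alone; camera adjusted p = 1.4e-08, adjusted p = 0.386 with an estimated correlation). Of 72 cytosolic ribosomal protein genes 2 rose (4 adjusted over the list alone), with camera adjusted p = 0.0045, adjusted p = 0.871 with an estimated correlation. The activating receptor gene Ncr1 (1.60), Klrc2 (1.65), the granzyme gene Gzmb (1.12), Stx11 (1.54), the NK cell transcription factor gene Nfil3 (1.22), the cyclin gene Ccnd2 (1.77) and the elongation factor gene Supt6 (0.99) rose in lists that did not pass as lists. After rescaling cytotoxic effectors passed (camera adjusted p = 0.041, adjusted p = 0.244 with an estimated correlation).

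Both cytokines together raised 226 windows and lowered 7 (limma, 214 distinct places; edgeR 233, DESeq2 223). Of the 226 raised windows, 41 were also raised by IL-12 alone, 47 by IL-18 alone and 141 by neither. The median was 0.25 and became -0.07 after rescaling, with 395 raised and 349 lowered. Rescaling gave 744 calls, edgeR with TMM factors 835 and a fit on the compared groups only 1109. The count was 565 without IL-12 replicate 1, 358 without IL-12 replicate 3, 103, 119 and 137 without the replicates 1, 2 and 3 that received both cytokines, and 127 and 108 without unstimulated replicates 2 and 3.

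What IL-18 added to IL-12 was read from both cytokines against IL-12 alone. Tagap, a GTPase-activating protein gene (chromosome 17, 7925500 to 7926500), rose from 10.9 ± 2.70 to 62.3 ± 11.7 signal (n = 3 each, log2 2.41 ± 0.33, limma adjusted p = 2.1e-09), and Ifng rose by 1.50 ± 0.28 (limma adjusted p = 0.00012). Zhx2, Cyba, Gadd45b, the AP-1 factor gene Batf, Cd69, Pwp1, Slc11a1, Cd83 and Noxa1 rose by 2.08, 2.01, 1.94, 1.93, 1.84, 1.79, 1.77, 1.74 and 1.70. The potassium channel gene Kcnj8 fell by log2 -1.31 and Rnf125 by -1.16; DESeq2 ended both calls (adjusted p = 0.058 and 0.14), and edgeR that of Rnf125 (0.093). The NF-kB/MyD88 list had 9 of 24 raised (11 adjusted over the list alone; camera adjusted p = 1.4e-21), the IL-12/STAT4 list 4 of 21 (5 adjusted over the list alone; 2.3e-09), with Il2ra (1.63) and Zbtb32 (1.40), and cytokines and chemokines 5 of 12 (6 adjusted over the list alone; 3.8e-09), with Csf2 (1.42) and Cxcl10 (1.33); for all 3, adjusted p = 0.329 with an estimated correlation. Immediate-early genes (2 of 27 raised, 3 adjusted over the list alone), cytosolic ribosomal proteins (0 of 72, 0 adjusted over the list alone) and JAK-STAT feedback (0 of 18, 1 adjusted over the list alone) also passed upward (camera adjusted p = 1.4e-05, 0.00060 and 0.040, adjusted p = 0.997 for each with an estimated correlation). In all 62 windows rose and 2 fell (limma, 59 distinct places; edgeR 56, DESeq2 48; rescaled 226 raised and 132 lowered, 358 in total; edgeR with TMM factors 350). The count was 42, 29 and 143 without IL-12 replicates 1, 2 and 3, and 18, 23 and 41 without the replicates 1, 2 and 3 that received both cytokines.

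What IL-12 added to IL-18 was read from both cytokines against IL-18 alone. Ifng rose by log2 2.54 ± 0.28 (n = 3 each, limma adjusted p = 4.7e-15), Ifi203 by 1.88, Serpina3f by 1.83, Socs3 by 1.82, Thy1 by 1.79, Bcl6 by 1.72, the ETS factor gene Etv6 by 1.63, Gpr146 by 1.62 and Ccnd2, a cyclin of early cell cycle entry, by 1.53. The proprotein convertase gene Furin rose by 1.69, a call that DESeq2 ended (adjusted p = 0.070). The IL-12/STAT4 list had 8 of 21 raised (12 adjusted over the list alone; camera adjusted p = 5.5e-34, adjusted p = 0.0433 with an estimated correlation), while the NF-kB/MyD88 list had 0 of 24 raised and did not pass. JAK-STAT feedback had 3 of 18 raised, cytokines and chemokines 1 of 12, interferon-stimulated genes 1 of 21 (Gbp2, 1.52) and immediate-early genes 0 of 27 (4, 4, 1 and 0 adjusted over the list alone; camera adjusted p = 9.9e-06, 4.9e-08, 0.0015 and 0.00036, adjusted p = 0.658, 0.50, 0.881 and 0.921 with an estimated correlation). Arl4d, Tmem216 and Etv4 had log2 -0.91, -1.19 and -1.07 (limma adjusted p = 0.18, 0.23 and 0.26) on the authors' scale. All 3 fell after rescaling and with edgeR and TMM factors (adjusted p = 3.1e-12, 0.014 and 0.013), and Arl4d also in a limma fit on the compared groups only (adjusted p = 0.021). In all 37 windows rose and 0 fell (limma, 37 distinct places, 307 with unadjusted p < 0.05; edgeR 34, DESeq2 37; rescaled 122 raised and 44 lowered, 166 in total; edgeR with TMM factors 216; compared groups only 72). The count was 71 and 58 without IL-12 replicates 1 and 3, 12 and 18 without the replicates 1 and 2 that received both cytokines, and 13 and 16 without IL-18 replicates 2 and 3.

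**Figure D1:**
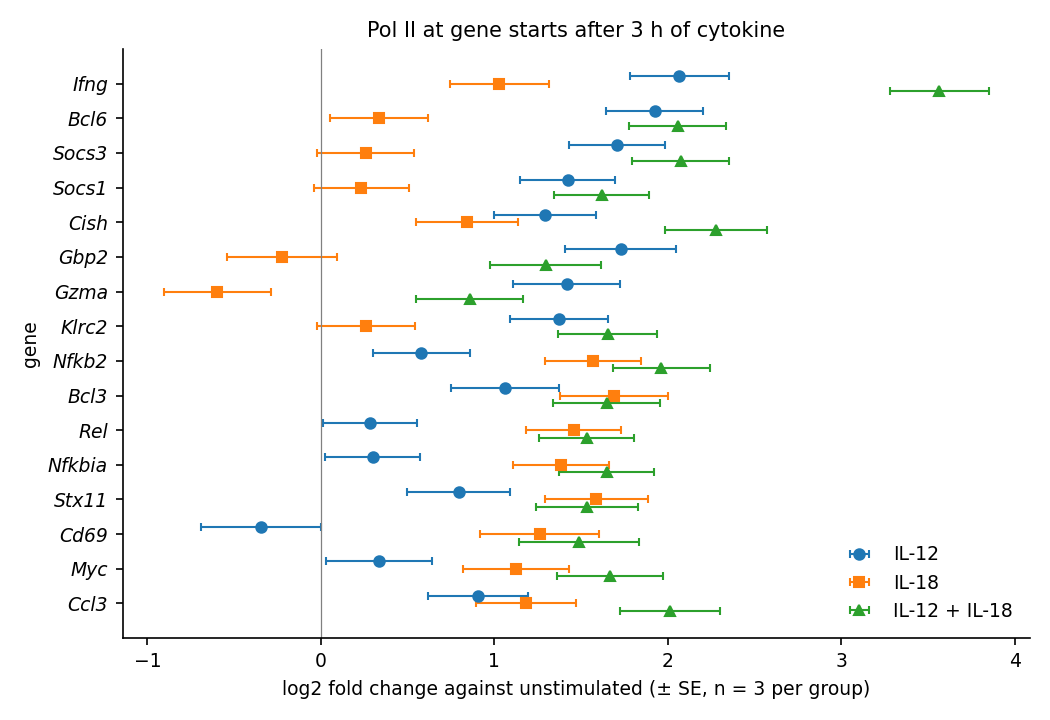
Log2 fold change of deposited signal against unstimulated cells (x axis) for 16 genes (y axis) under IL-12, IL-18 and both at 3 h, n = 3 libraries per group; points are limma estimates and bars their SE. Ifng lies at 2.07, 1.03 and 3.56.

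Whether the effect of both cytokines at 3 h exceeded the sum of the single effects was tested as a departure from additivity on the log2 scale. There a sum of effects is a product of fold changes, and additivity of the signal itself was not tested. Ifng had 23.2 signal unstimulated, 102 with IL-12, 48.4 with IL-18 and 289.6 with both. Ifng departed by log2 0.47 ± 0.40 (n = 3 per group, limma adjusted p = 1.0). Tagap departed by 2.11 ± 0.47 (limma adjusted p = 0.069) and passed after rescaling (2.22, limma adjusted p = 0.00044), with edgeR and TMM factors (3.1e-05) and with a limma pseudocount of 10 (0.032). The glycoprotein gene Thy1 had 1.83 ± 0.57, Fes 1.53, Tmem216 -1.85, Stoml1 -1.46 and the lysosomal trafficking gene Lyst -1.24. In all 0 windows passed (limma; 127 with unadjusted p < 0.05; edgeR 0, DESeq2 0), no list passed, and 1 window passed after rescaling. The count was 1 without IL-12 replicate 1, IL-12 replicate 3, IL-18 replicate 1 or unstimulated replicate 2. The 127 windows are less than a share of 0.05 of the 8873 tested, the share expected without any effect. An absence of calls is thus weak evidence of additivity. The windows raised by each cytokine alone shared 3 genes, Fas, Ifng and Pim2, against 0.36 expected if the calls were independent. Both effects use the same 3 unstimulated libraries. In 100 simulated tables without any cytokine effect they therefore correlated at 0.50 on average, and the measured correlation was 0.37. Because the simulation held no cytokine effect, these correlations cannot tell whether the responses are related. The shared number was 39 after rescaling, 36 with edgeR and TMM factors, 1 with DESeq2, 1 with a pseudocount of 10 and 1 at adjusted p < 0.01. It was 24 without IL-12 replicate 1 and 1 without IL-18 replicate 2, unstimulated replicate 2 or unstimulated replicate 3.

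In the Stat4 study the first question was what IL-12 does within 15 min in wild-type cells. Ifng rose from 10.9 ± 2.78 to 107 ± 28.8 signal (mean ± SD, n = 2 each, log2 3.18 ± 0.40, limma adjusted p = 9.4e-13; rescaled 2.37, limma adjusted p = 6.6e-06). Utp23, a ribosome assembly gene (chromosome 15, 51876929 to 51877929), rose from 4.69 ± 6.63 to 85.6 ± 8.23 (4.74 ± 0.42, rescaled 4.12). Its libraries had 0 and 8 reads unstimulated and 66 and 98 with IL-12, so the size of this rise rests on the pseudocount and 1 library. Il18rap, a subunit of the IL-18 receptor (chromosome 1, 40514862 to 40515862), rose from 8.70 ± 4.01 to 92.9 ± 32.2 (3.30 ± 0.40, rescaled 2.49). Uqcrc2, Nsmce1, Rhoq, Nsun4, Gpr146, Lsm4 and Sytl3 rose by 3.41, 3.00, 2.96, 2.87, 2.85, 2.83 and 2.78 (rescaled 2.67, 2.21, 2.14, 2.05, 2.07, 2.00 and 1.96), with Uqcrc2 encoding part of the respiratory chain; Gpr146 was not called once the highest-total library was left out and the others rescaled (limma adjusted p = 0.11). Falls were not called on the authors' scale: the calcium channel gene Trpv2 had log2 -0.84 (limma adjusted p = 0.080; rescaled -1.62, limma adjusted p = 0.020) and Aloxe3 -0.70 (limma adjusted p = 0.15). Eif2s3y had 0 reads after IL-12 against 2 without, below the floor of 3 reads per library, so no fall can be read there although a limma fit on the compared groups only called it (adjusted p = 9.1e-11). With edgeR and TMM factors 7 windows fell, among them Trpv2 (-1.44, adjusted p = 0.030) and Aloxe3 (-1.50, adjusted p = 0.034).

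In the IL-12/STAT4 list 10 of 12 genes rose within 15 min in these wild-type cells (11 adjusted over the list alone; 7 rescaled), among them Cish (log2 2.51, rescaled 1.72), Serpina3g (2.50, rescaled 1.72), Socs3 (2.37, rescaled 1.55) and Bcl6 (2.23, rescaled 1.40). The list moved up (limma camera adjusted p = 4.0e-22, adjusted p = 0.0889 with an estimated correlation). Interferon-stimulated genes had 8 of 11 raised (9 adjusted over the list alone; 1 rescaled), including Gbp2 (2.48, rescaled 1.69), the MHC class I activator gene Nlrc5 (2.21) and Irf1 (1.74), with Nlrc5 (1.45) and Irf1 (0.92) not past the threshold after rescaling (limma adjusted p = 0.099 and 0.12). Its limma camera test passed upward (adjusted p = 0.00046, adjusted p = 0.35 with an estimated correlation). JAK-STAT feedback had 8 of 14 raised (8 adjusted over the list alone; 3 rescaled), with the phosphatase gene Ptpn2 (1.91, rescaled 1.08), and cytokines and chemokines 2 of 3 (2 adjusted over the list alone; 1 rescaled), with camera adjusted p = 0.0019 and 0.0037, adjusted p = 0.616 and 0.207 with an estimated correlation. Lists that did not move against the other windows still had raised members, such as 24 of 61 cytosolic ribosomal protein genes (0 rescaled), 13 of 19 DEAD-box helicases (1 rescaled) and 11 of 23 Pol II machinery genes (0 rescaled).

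In all 2058 of 5218 windows rose and 0 fell (limma, 1723 distinct places; 2930 with unadjusted p < 0.05; edgeR 2258, DESeq2 1515). The median log2 change was 0.78 and became -0.03 after rescaling, with 60 raised and 4 lowered. The count was thus 64 rescaled, 92 with edgeR and TMM factors, 38 rescaled and without the highest-total library, and 164 with a fit on the compared groups only. It was 794 and 804 without IL-12 knockout replicates 1 and 2, 1219 and 1226 without unstimulated knockout replicates 1 and 2, 3900 and 493 without IL-12 wild-type replicates 1 and 2, and 652 and 186 without unstimulated wild-type replicates 1 and 2.

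In Stat4 knockout cells IL-12 for 15 min left Ifng at 12.5 ± 4.61 against 14.9 ± 4.92 signal (n = 2 each, log2 -0.25 ± 0.40, limma adjusted p = 1.0). The smallest p-values belonged to Nlrc5 (1.52 ± 0.44), the ferritin receptor gene Ncoa4 (1.35), Gpcpd1 (1.23), Tmem140 (-1.22), Prune1 (-1.11) and the protease gene Pcsk7 (-1.08), none past the threshold. In all 0 windows passed (limma, 111 with unadjusted p < 0.05, edgeR 0, DESeq2 0, edgeR with TMM factors 0), with a median of 0.07, and no list passed. The 111 windows are less than a share of 0.05 of the 5218 tested, so 0 calls are weak evidence of no effect.

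The difference of the IL-12 effect between Stat4 knockout and wild type was tested as an interaction. For Utp23, with 0 and 8 reads in the unstimulated wild-type libraries, the size of the difference rests on the pseudocount and 1 library. Utp23 differed by log2 -4.47 ± 0.60 (n = 2 per group, limma adjusted p = 3.9e-10; rescaled -3.90), Il18rap by -3.99 ± 0.56 (3.5e-09; rescaled -3.26), the genome stability gene Nsmce1 by -3.75 ± 0.58 (1.2e-07; rescaled -3.03), Ifng by -3.43 ± 0.56 (8.3e-07; rescaled -2.69) and Nsun4 by -3.17 ± 0.51 (5.5e-07; rescaled -2.41). In the IL-12/STAT4 list 3 of 12 genes had a smaller effect in the knockout, Il18rap, Ifng and Irf8 (-2.07), with 9 adjusted over the list alone (2 rescaled). As a list these passed downward (limma camera adjusted p = 3.3e-10, adjusted p = 0.26 with an estimated correlation). Cytokines and chemokines had 1 of 3 (1 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.26 with an estimated correlation), and the list did not pass after rescaling (camera adjusted p = 0.13). Gbp2 (-2.37), the GTPase gene Gbp7 (-2.30) and Ptpn2 (-2.06) also differed. After rescaling Ptpn2 still did (-1.30), but Irf8 (-1.32), Gbp2 (-1.64) and Gbp7 (-1.59) did not pass (limma adjusted p = 0.25, 0.34 and 0.41). Fbxl17 (1.39, limma adjusted p = 0.17) and the overlapping pair Sclt1 (1.13) and D3Ertd751e (1.14) had positive values that did not pass. With edgeR and TMM factors Fbxl17 passed (2.29, adjusted p = 0.035), the 1 larger effect in the knockout among 28 calls. In all 77 windows had a smaller effect in the knockout and 0 a larger one (limma, 66 distinct places, 1212 with unadjusted p < 0.05; edgeR 69, of which 65 shared with limma; DESeq2 97, of which 21 shared, with no adjusted p for 4350 windows; rescaled 17; edgeR with TMM factors 28), and the median of -0.72 became 0.03 after rescaling. The count was 15 and 19 without IL-12 knockout replicates 1 and 2, 27 and 16 without unstimulated knockout replicates 1 and 2, 2384 without IL-12 wild-type replicate 1 and 21 without unstimulated wild-type replicate 2.

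Unstimulated Stat4 knockout cells differed from wild type mainly at genes of the Y chromosome. Ddx3y, a helicase gene, had 30.3 ± 4.36 signal against 0 (n = 2 each, 69 against 0 reads, at least 8.22-fold higher; limma adjusted p = 4.5e-22), and the demethylase gene Uty 24.9 ± 1.23 against 0 (57 against 0 reads, at least 6.75-fold higher). Eif2s3y, a translation initiation factor gene, had 47.2 ± 3.38 against 1.28 ± 1.81 (108 against 2 reads, a ratio of 38.3 with a counting interval of 10.4 to 321). Bzw1, a regulator of translation initiation (chromosome 1, 58392398 to 58393398), fell from 29.8 ± 7.66 to 4.23 ± 1.94 (log2 -2.59 ± 0.43, limma adjusted p = 1.8e-06), a call DESeq2 ended (adjusted p = 0.052). The libraries with IL-12 also had less Bzw1 signal in the knockout, 3.66 ± 0.735 against 28.0 ± 10.5 in wild type (n = 2 each). Parp9 rose by 1.82 ± 0.44 (limma adjusted p = 0.024) in a window shared with Dtx3l, and edgeR (adjusted p = 1.0), DESeq2 (1.0), rescaling in limma (0.14) and a limma pseudocount of 10 (1.0) ended the call. Ifng had 0.40 ± 0.40 (limma adjusted p = 1.0). In all 5 windows rose and 1 fell (limma, 6 distinct places; edgeR 5, DESeq2 4; rescaled 4 and 2), no list passed, and without windows on X and Y the count was 1. The table has no window at Stat4, so the knockout itself could not be read from it.

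In the Ddx5 study IL-12 for 15 min in wild-type cells was tested again. Ifng rose from 19.4 ± 5.36 to 145 ± 6.98 signal (n = 2 each, log2 2.86 ± 0.34, limma adjusted p = 7.9e-06). Icam1, an adhesion molecule gene, rose from 4.64 ± 6.56 to 34.4 ± 3.22 (3.46 ± 0.66, limma adjusted p = 0.0030). The SD of its unstimulated libraries exceeded their mean, so the size of this rise is uncertain. Serpina3f had 79 against 3 reads (a ratio of 14.5 with a counting interval of 4.77 to 71.6; limma adjusted p = 0.0011) and Nudt13 66 against 3 (12.1, 3.96 to 60.1; limma adjusted p = 0.0072). Gpr146 rose by 3.02, the lysosomal protease gene Ctsb by 2.98, Ankrd28 by 2.91 and Arl1, in a window shared with Gm4925, by 2.81. The cytokine receptor gene Il6st (2.92), Rap1gds1 (2.90) and the mitochondrial carrier gene Slc25a5, which fell by log2 -1.54, passed (limma adjusted p = 0.040, 0.038 and 0.042) but not after rescaling (0.069, 0.098 and 0.073). Without the 2 shallow libraries they had 1.56, 1.29 and -1.18 and did not pass (limma adjusted p = 0.10, 0.061 and 0.066).

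The IL-12/STAT4 list had 7 of 18 genes raised in these cells (13 adjusted over the list alone), with Cish (log2 2.34), Socs3 (2.11) and Il18rap (1.98). The list moved up (limma camera adjusted p = 8.4e-24, adjusted p = 0.0837 with an estimated correlation). Interferon-stimulated genes had 5 of 20 raised (9 adjusted over the list alone), Gbp2 (2.58), Nlrc5 (2.00), Gbp7 (1.95) and the antigen-processing genes Psmb9 (1.32) and Tap1 (1.30). Its limma camera test passed upward (adjusted p = 2.1e-11, adjusted p = 0.16 with an estimated correlation). JAK-STAT feedback had 3 of 17 raised, cytokines and chemokines 1 of 6, the NF-kB/MyD88 list 1 of 22 (Icam1) and NK cell transcription factors 0 of 15 (5, 1, 3 and 2 adjusted over the list alone; camera adjusted p = 0.0013, 0.00036, 0.010 and 0.011, adjusted p = 0.692, 0.108, 0.753 and 0.753 with an estimated correlation). The granule membrane gene Nkg7 rose by 1.24. In all 93 of 7916 windows rose and 1 fell (limma, 82 distinct places; edgeR 121, DESeq2 39; median -0.06; rescaled 130 raised and 1 lowered; edgeR with TMM factors 269; 196 without the 2 shallow libraries). The count was 7 without IL-12 wild-type replicate 1, 7 without IL-12 wild-type replicate 2, 20 without unstimulated wild-type replicate 1 and 297 without unstimulated wild-type replicate 2.

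In Ddx5 knockout cells IL-12 for 15 min raised Ifng from 16.7 ± 2.89 to 148.6 ± 69.4 signal (n = 2 each, log2 3.01 ± 0.34, limma adjusted p = 2.5e-06; rescaled 3.13). Tafa3 rose from 1.63 ± 0.644 to 35.2 ± 18.0 (3.71 ± 0.57, limma adjusted p = 0.00049), Gpr146 by 2.87, Nlrc5, in a window shared with 9330175E14Rik, by 2.86, and Myd88, the adaptor of the IL-18 receptor, by 2.34. The interferon receptor gene Ifnar2 (2.82), Bin3 (2.44) and Ctsb (2.27) rose, but not in a limma fit on the compared groups only (adjusted p = 0.052, 0.14 and 0.058). Zfp429 (2.72), the chromatin remodeller gene Chd6 (-2.80), the splicing factor gene Srsf9 (-1.97) and Tram1 (-1.97) passed in limma but not after rescaling (adjusted p = 0.065, 0.16, 0.11 and 0.21) or with DESeq2 (adjusted p = 0.11, 0.78, 0.56 and 0.97). Without the 2 shallow libraries Chd6 had -1.17 and Tram1 -0.73, and with edgeR and TMM factors -1.25 and -0.74, none past the threshold. Pol II at Ddx5 itself (chromosome 11, 106788032 to 106789032, shared with Cep95) had -0.18 ± 0.25 with IL-12 in the knockout and -0.10 ± 0.25 in wild type, and its paralogue Ddx17 -0.02 and -0.05.

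The IL-12/STAT4 list had 5 of 18 genes raised in the Ddx5 knockout (11 adjusted over the list alone), with Cish (log2 2.12), Socs3 (2.07) and Il18rap (1.65). As a list these passed upward (limma camera adjusted p = 1.1e-25, adjusted p = 0.0726 with an estimated correlation). Interferon-stimulated genes had 3 of 20 raised (7 adjusted over the list alone), Nlrc5, Gbp7 (2.17) and Gbp2 (1.92). The list moved up (limma camera adjusted p = 8.6e-13, adjusted p = 0.132 with an estimated correlation). JAK-STAT feedback had 2 of 17 raised, cytokines and chemokines 1 of 6, the NF-kB/MyD88 list 1 of 22 (Map3k8, 1.52), cytotoxic effectors 0 of 13 and NK cell transcription factors 0 of 15 (4, 1, 1, 2 and 0 adjusted over the list alone; camera adjusted p = 0.00079, 5.8e-05, 0.0041, 0.015 and 0.046, adjusted p = 0.651, 0.0769, 0.773, 0.69 and 0.936 with an estimated correlation). Immediate-early genes passed only after rescaling (camera adjusted p = 0.032, adjusted p = 0.199 with an estimated correlation). In all 48 windows rose and 3 fell (limma, 41 distinct places; edgeR 136, with 104 raised and 32 lowered, DESeq2 40, all raised). The median was -0.21 and became -0.09 after rescaling, with 90 raised and 1 lowered, 91 in total. The count was 80 with a pseudocount of 10, 274 with edgeR and TMM factors (245 raised and 29 lowered), 13 with a fit on the compared groups only and 181 without the 2 shallow libraries. It was 375 and 1 without IL-12 knockout replicates 2 and 3, 19 and 12 without unstimulated knockout replicates 1 and 3, and 17 without either IL-12 wild-type replicate 1 or 2.

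The difference of the IL-12 effect between Ddx5 knockout and wild type was again tested as an interaction. Ifng differed by log2 0.14 ± 0.48 (n = 2 per group, 95% interval -0.84 to 1.13; limma adjusted p = 1.0), Ddx5 by -0.08 ± 0.35 and Ddx17 by 0.02. Bcl2l15 (1.94), Mipol1 (1.48), Slc25a5 (1.37), the chromatin remodeller gene Arid1a (-2.03), the ribosomal protein gene Rpl32 (-1.65) and Rap1gds1 (-4.45 ± 1.04) had the smallest p-values without passing. Rap1gds1 passed with a limma pseudocount of 10 (adjusted p = 0.016) and with the replicate number as block (-5.30, limma adjusted p = 0.00069). In all 0 windows passed (limma; 254 with unadjusted p < 0.05; edgeR 0, DESeq2 0, edgeR with TMM factors 0), with a median of -0.17 (rescaled -0.08), and no list passed. The count was 1 with a pseudocount of 10, 1 without the 2 shallow libraries, 22 without IL-12 knockout replicate 2 and 51 without unstimulated wild-type replicate 2.

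Unstimulated Ddx5 knockout and wild-type cells had 415 ± 60.4 and 364 ± 82.4 signal at Ddx5 (n = 2 each, log2 0.20 ± 0.25, limma adjusted p = 0.98). Ddx17 had 0.00 and Ifng -0.19 ± 0.34. The sirtuin gene Sirt7 (2.87), Rap1gds1 (2.60), Atcayos (1.50), the integrin gene Itga1 (-1.51), the lipid transfer gene Osbpl1a (-1.67) and Bcl2l15 (-1.37) had the smallest p-values without passing. Sirt7 passed only with the replicate number as block (3.56, limma adjusted p = 0.00079). In all 0 windows passed (limma; 347 with unadjusted p < 0.05; edgeR 0, DESeq2 0, edgeR with TMM factors 0), no list passed, and the median of 0.20 became 0.03 after rescaling. Without unstimulated wild-type replicate 2 the count was 288.

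**Figure D2:**
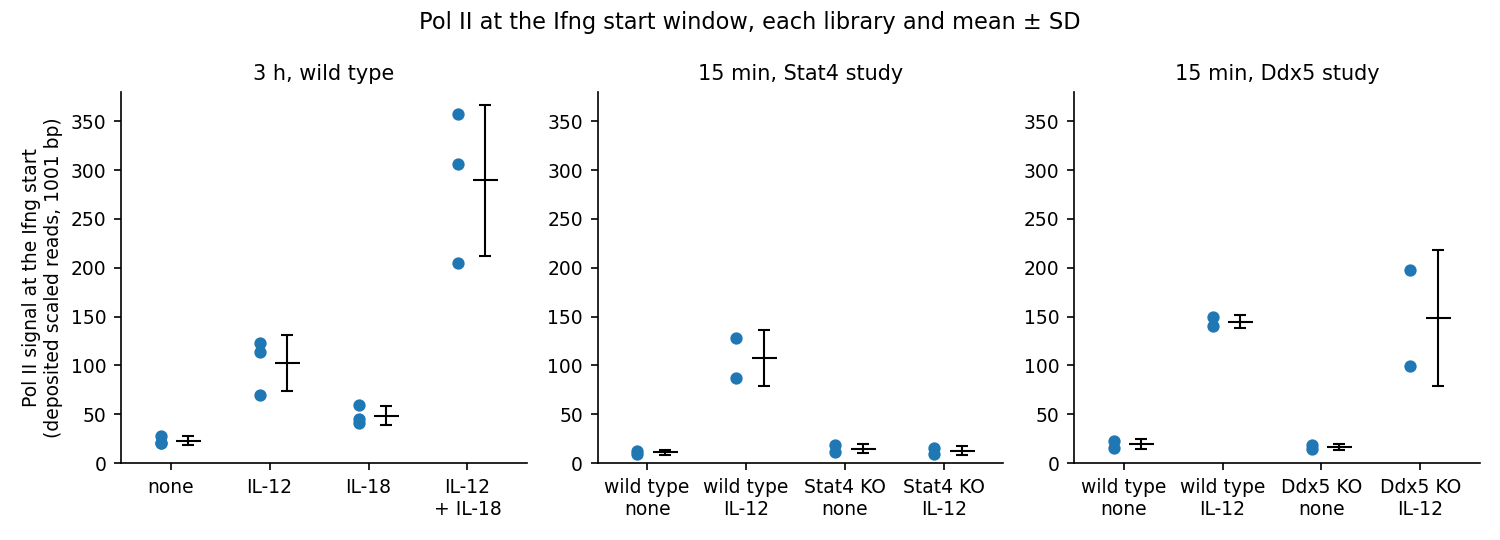
Deposited signal at Ifng (y axis) in each library by group (x axis), 1 panel per table; points are libraries and bars the mean ± SD. IL-12 raised Ifng to 107 in wild type of the Stat4 study, 145 in wild type of the Ddx5 study and 148.6 in the Ddx5 knockout.

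The 55 genes raised by IL-12 at 3 h were followed into the 15 min tables. In wild type of the Stat4 study 47 were measured, all 47 had positive values, 40 rose, and their median of log2 1.49 lay 0.71 above all windows (limma camera p = 9.0e-41, p = 0.013 with an estimated correlation). Only 91 of the 5218 windows were negative there and 2058 rose. Positive values were thus nearly certain, and 18.7 raised genes were expected if the calls were independent. In Stat4 knockout cells the median of these 47 genes was 0.11 (camera p = 0.21), and in the interaction -1.52, 0.81 below all windows (p = 1.0e-22, p = 0.036 with an estimated correlation). In the Ddx5 study 54 were measured, with a median of 0.94 in wild type (19 rose; camera p = 8.9e-49) and 0.69 in the knockout (11 rose; p = 2.1e-42), p = 0.019 and 0.024 with an estimated correlation, and -0.23 in the interaction (difference to all windows -0.06, p = 0.17). That last difference was -0.27 without the 2 shallow libraries and -0.25 without IL-12 knockout replicate 3, which is 1 of these 2. It was -0.15 without IL-12 wild-type replicate 1. The small difference with all libraries thus rests in part on a shallow library. Without IL-12 replicate 1 of the 3 h table, when the list was redrawn from 685 calls, its genes lay 0.12 above all windows in wild type of the Stat4 study and -0.05 from them in its interaction, and 0.17 and 0.21 above in wild type and knockout of the Ddx5 study. The list redrawn without IL-12 replicate 2 of that table gave -0.47 in the Stat4 interaction. In wild type of the Stat4 study the distance of the redrawn lists was 1.14 without IL-12 replicate 3 of the 3 h table, and 1.10 to 1.20 without any of its unstimulated replicates, the replicates that received both cytokines or IL-18 replicate 3. After rescaling, the 190 genes raised at 3 h had medians of 0.27 in wild type of the Stat4 study, 0.07 in its knockout (up against all windows, limma camera p = 0.00025, p = 0.022 with an estimated correlation), -0.20 in its interaction, and 0.42 and 0.34 in wild type and knockout of the Ddx5 study.

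Lists drawn at 15 min were followed from 1 study into the other. The 93 genes raised in wild type of the Ddx5 study, Ifng, Gpr146 and Il18rap among them, had a median of log2 1.79 in wild type of the Stat4 study (62 measured, 60 raised against 24.6 expected if the calls were independent), 0.24 in its knockout (limma camera p = 0.0029, p = 0.36 with an estimated correlation) and -1.62 in its interaction (p = 3.2e-30, p = 0.017 with an estimated correlation). These genes lay 1.00, 0.17 and -0.91 from all windows. Lists were redrawn when a library of the study that defines them was left out: without unstimulated wild-type replicate 2 of the Ddx5 study, which gave 297 calls, the redrawn list lay 0.42, 0.03 and -0.37 from all windows. The knockout value was 0.33 without unstimulated Stat4 knockout replicate 1 and 0.10 for the list redrawn without IL-12 wild-type replicate 1 of the Ddx5 study. The 2058 genes raised in wild type of the Stat4 study had a median of -0.03 in wild type of the Ddx5 study (2041 measured, 0.03 above all windows, camera p = 0.036, p = 0.75 with an estimated correlation). For lists redrawn with each library left out this distance ranged from about 0 to 0.717, the latter for the 186 calls without unstimulated wild-type replicate 2 of the Stat4 study. After rescaling, the list held 60 genes, with medians of 1.15 in wild type and 1.03 in knockout cells of the Ddx5 study.

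**Figure D3:**
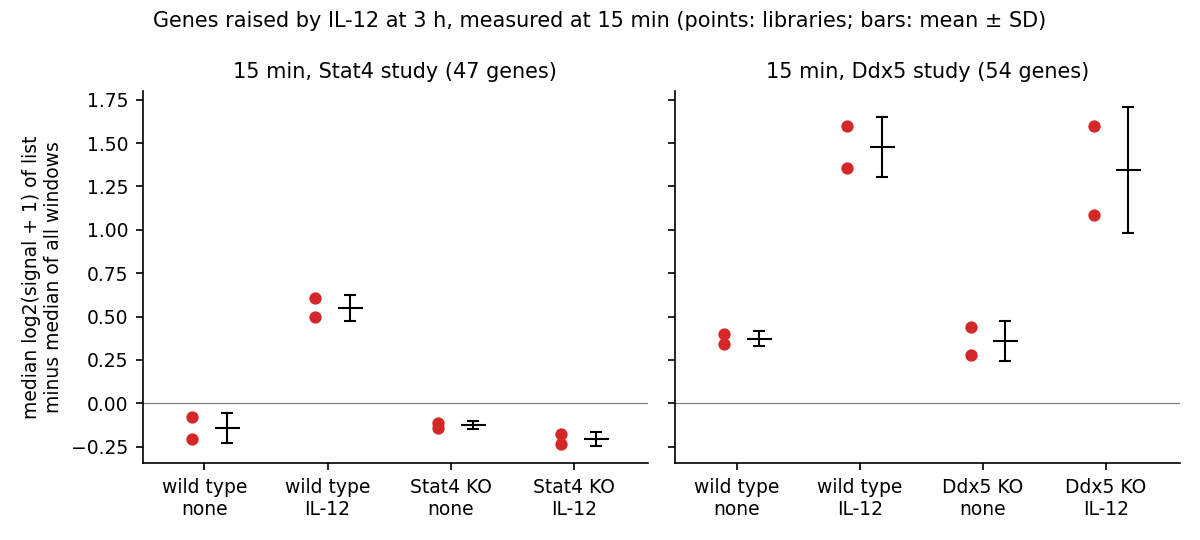
Score of the genes raised by IL-12 at 3 h (y axis, median log2(signal + 1) of the list minus that of all windows) in each 15 min library by group (x axis), 47 genes in the Stat4 study and 54 in the Ddx5 study; points are libraries. Scores in the Stat4 study were 0.60 and 0.50 for wild type with IL-12 and -0.18 and -0.24 for the knockout with IL-12.

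The 60 genes raised at 15 min in wild type of both studies, against 24.6 by chance, were followed to 3 h. After rescaling both studies shared 43 raised genes, and without either IL-12 wild-type library of the Ddx5 study the set could hold at most 7. At 3 h 59 of them were tested, all 59 had positive values with IL-12, 19 rose, 40 did not pass, and the median was log2 0.72. After rescaling 54 were positive and 5 negative, 25 rose, 34 did not pass, and the median was 0.47. Utp23 was among the 40 with 4.74 and 2.36 at 15 min and 0.46 at 3 h (rescaled 4.12 in the Stat4 study and 0.21 at 3 h), as were Il18rap with 3.30, 1.98 and 0.89 (rescaled 2.49, 2.02 and 0.63), the kinase gene Fastk with 2.14, 2.10 and 0.27 (rescaled 1.33, 2.14 and 0.01) and the IL-6 family cytokine gene Osm with 1.99, 1.70 and 0.53 (rescaled 1.20, 1.74 and 0.28). After rescaling Il18rap passed at 3 h (limma adjusted p = 0.00031) and Osm did not pass in the Stat4 study (limma adjusted p = 0.11). In Stat4 knockout cells Il18rap had -0.69, Utp23 0.28, Osm 0.21 and Fastk 0.10, and 0 of the 60 passed. In Ddx5 knockout cells 26 passed, and Utp23 had 1.91, Il18rap 1.65, Osm 1.40 and Fastk 1.44. The genes in this paragraph were chosen after the values were seen, and the time points differ in antibody and batch as well as in duration. Wild-type libraries of the Stat4 study also had far fewer Y-chromosome reads than those of the other tables.

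Lists that never moved against the other windows in any comparison were cell cycle (smallest limma camera adjusted p = 0.16), glycolysis (0.32), NK cell receptors (0.18), Pol II machinery (0.091), DEAD-box helicases (0.091) and T cell markers (0.091). Single members did rise, such as Klrc2 under IL-12 at 3 h (log2 1.37). B cell and erythroid markers had 0 tested windows in every table. ILC2/ILC3 markers had 2 at 3 h (Gata3 and Kit), 0 in the Stat4 study and 2 in the Ddx5 study (Gata3 and Icos), too few for a list test. T cell markers had 1 (Cd28) and myeloid markers 1 (Cd68) and 2 (Cd68 and Cebpb) in the Stat4 and Ddx5 studies, where these lists were not tested.

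**Figure D4:**
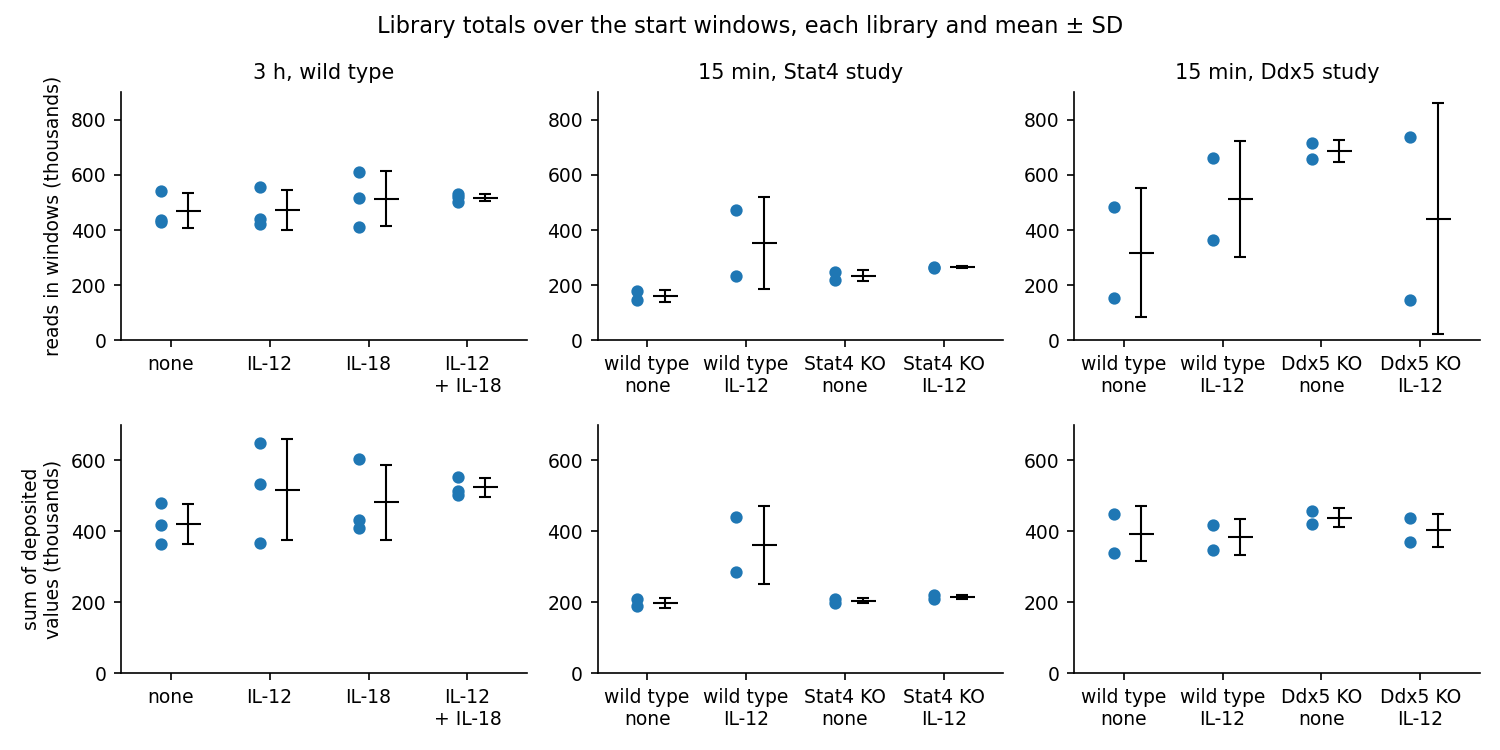
Recovered reads (upper panels) and sums of deposited signal (lower panels), both in k on the y axis, for each library by group (x axis); points are libraries and bars the mean ± SD. In the Stat4 study wild-type libraries with IL-12 had deposited sums of 283912 and 440009 signal against 208153 and 188233 without.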

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

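The interaction and the following of gene lists across tables were planned, and rescaling these lists, edgeR with TMM factors and leaving out libraries for the lists were chosen after the result was seen.

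For the Stat4 study, 77 windows differed in their IL-12 effect between knockout and wild type, all with the smaller effect in the knockout (limma interaction on the authors' scale, n = 2 libraries per group). The count was 17 after rescaling, 28 with edgeR and TMM factors (1 of them larger in the knockout), and 15 to 2384 with each library left out. The largest were Utp23 (log2 -4.47), Il18rap (-3.99), Nsmce1 (-3.75), Ifng (-3.43) and Nsun4 (-3.17). Utp23 had 0 and 8 reads in the unstimulated wild-type libraries, so its value and first place rest on the pseudocount and 1 library. These windows were picked out because the difference itself was tested by interaction, rather than by 1 genotype passing and the other not.

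The genes raised by IL-12 at 3 h had a median interaction of -1.52 in the Stat4 study, and those raised at 15 min in wild type of the Ddx5 study -1.62. The median of all windows was -0.72, so part of each value is the table-wide shift. After rescaling the medians of the rescaled lists were -0.20 and -0.82. With lists redrawn, the distance to all windows was -0.05 for the first without IL-12 replicate 1 of the 3 h table and -0.37 for the second without unstimulated wild-type replicate 2 of the Ddx5 study. For the planned lists of the 200 smallest p this distance was -0.29 and -0.72 (limma camera with an estimated correlation, p = 0.17 and 0.034). These medians were picked out because lists drawn from other tables moved in the interaction against all windows (limma camera, two-sided).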

How the results depend on the processing

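The settings added after the result was seen were edgeR with TMM factors, the refits without the 2 shallow libraries, without windows on X and Y and without the highest-total library of the Stat4 study, rescaling for the list tests, and the settings of the cross-table and overlap results other than a list of the 200 smallest p and an overlap at adjusted p < 0.01; the others were planned. The cause was not tested for any change below, except that fewer libraries or windows enter where some are left out. The planned average over several windows of 1 gene was not run, because each gene identifier has 1 window per table.

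With every library rescaled to the same total the counts were 300 for IL-12 at 3 h (55 as deposited), 326 for IL-18 (60), 744 for both (233), 358 for both against IL-12 (64), 166 for both against IL-18 (37), 1 for the departure from additivity (0), 64 for IL-12 in wild type of the Stat4 study (2058; 38 also without the highest-total library), 17 for the Stat4 interaction (77), 91 in the Ddx5 knockout (51) and 39 for the overlap of IL-12 and IL-18 (3). With edgeR and TMM factors the same 10 results gave 282, 341, 835, 350, 216, 1, 92, 28, 274 and 36, and wild type of the Ddx5 study gave 269 (94). A fit on the compared groups only gave 22 for IL-12 at 3 h, 1109 for both, 72 for both against IL-18, 164 in wild type of the Stat4 study and 13 in the Ddx5 knockout. The replicate number as block gave 29 for IL-12 and 35 for IL-18 at 3 h, 5 for the Ddx5 interaction and 2 for unstimulated Ddx5 knockout against wild type (0 each without). Whether the replicate number pairs libraries stays open. Deviations of same-numbered libraries correlated at -0.035 to 0.074, none over 0.1. Their median correlation was 0.020 at 3 h, 0.033 in the Stat4 study and 0.027 in the Ddx5 study. For libraries of different number it was lower, at -0.006, -0.033 and -0.004. At 3 h 7 of 12 libraries were closest to their own number, in the Stat4 study 8 of 8 and in the Ddx5 study 5 of 8. Counting error lowers such correlations, so values under 0.1 cannot exclude pairing. DESeq2 gave 39 in wild type of the Ddx5 study and 1 for the overlap, and edgeR 136 in the Ddx5 knockout. A pseudocount of 10 gave 1 for the departure from additivity, 80 in the Ddx5 knockout, 1 for the Ddx5 interaction and 1 for the overlap, and adjusted p < 0.01 gave 1 for the overlap. Without the 2 shallow libraries the counts were 196 and 181 in wild type and knockout of the Ddx5 study and 1 for the Ddx5 interaction, and the 3 h IL-12 genes lay -0.27 from all windows in that interaction (-0.06 with all libraries). Without windows on X and Y unstimulated Stat4 knockout against wild type gave 1 (6). An estimated correlation left 2 of 49 list calls on the authors' scale and 29 of 49 after rescaling.

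Leaving out each library in turn gave 16 to 685 for IL-12 at 3 h, 22 to 107 for IL-18, 103 to 565 for both, 18 to 143 for both against IL-12, 12 to 71 for both against IL-18 and 0 to 1 for the departure from additivity. In the Stat4 study it gave 186 to 3900 in wild type, 0 to 0 in the knockout, 15 to 2384 for the interaction and 5 to 8 for unstimulated cells. In the Ddx5 study it gave 7 to 297 in wild type, 1 to 375 in the knockout, 0 to 51 for the interaction and 0 to 288 for unstimulated cells. List calls ranged from 45 to 51 and the overlap from 1 to 24. The 3 h IL-12 genes ranged from -1.0 to -0.05 in the Stat4 interaction and -0.25 to 0.0929 in the Ddx5 interaction, the genes raised at 15 min in the Ddx5 study from -0.92 to -0.37 in the Stat4 interaction, and those of the Stat4 study from -0.0427 to 0.0946 in the Ddx5 interaction. The latter, measured in wild type of the Ddx5 study, ranged up to 0.717 and reversed to -0.000190 without IL-12 wild-type replicate 1 of the Stat4 study. Where 1 library is left in a group, that lone sample is assumed to vary like the other groups.

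Of the named genes, edgeR on the authors' scale left 150 calls the same and made 4 weaker, DESeq2 143 and 11, no filter 147 and 7, and rescaling 138 the same, 8 weaker and 8 stronger. Over all left-out libraries 1385 were the same, 129 weaker and 14 stronger. Of the list calls, 484 were the same and 28 weaker over left-out libraries, and 47 the same and 2 weaker after rescaling. In the self-test 2-fold changes were recovered in 17% (4-fold 93%) of cases for IL-12 at 3 h, 14% (79%) and 6% (81%) in wild type of the Stat4 and Ddx5 studies, and 0% (29%) and 1% (35%) for their interactions. Small differences between genotypes were thus hardly ever recovered in these simulated tables. The rates hold for the authors' scale only and may be too low, because library spread entered the simulation through the dispersion as well.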

Other observations

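The tests on other splits of the libraries, on windows near Stat4, on power and on the response ratio were planned before the result was seen; those on the table-wide rise and on donor sex were chosen after the result was seen. All p-values of this section are two-sided.

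The table-wide rise in wild type of the Stat4 study, a median of log2 0.78 over 5218 windows against -0.0615 in wild type of the Ddx5 study, is open between biology and scale. Without IL-12 wild-type replicate 2 the median was 0.48, against an SD of library medians of 0.23, so the rise was smaller but did not vanish with that library. A lone IL-12 wild-type library was then left, so scatter between libraries stays open. A single scale factor would shift windows of all levels alike; the log2 ratio of summed signal rose from 0.70 in the lowest of 5 equal bins of windows to 0.92 in the highest, a difference of 0.22, against 0.20 between the IL-12 replicates themselves, so the test leaves a scale factor open. A broad rise of Pol II was not seen in the Ddx5 study, but that comparison is void if the factors of that study were set to equalise totals. The wild-type libraries of these studies also differed in Y-chromosome reads. Ifng and Il18rap passed on both scales.

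Y-chromosome genes separated unstimulated Stat4 knockout from wild type, with 262 and 237 Y reads in the unstimulated knockout libraries and 3 and 6 in the wild-type ones (293 and 294 against 7 and 12 with IL-12). Libraries of the 3 h table had 38 to 84 Y reads over 2 windows, and those of the Ddx5 study 67 to 450 over 5. Wild-type cells of the Stat4 study thus also differed from those of the other tables, which may enter any comparison of wild type across tables. Over all libraries, rescaled, 4 genes that escape X inactivation had a median of log2 -0.56 in the knockout against wild type (Kdm6a -0.95, Eif2s3x -0.63, Kdm5c -0.48, Ddx3x -0.17), but in unstimulated cells as deposited the median was -0.24 and 2 of the 4 were not lower (Kdm6a -1.08, Eif2s3x -0.50, Kdm5c 0.02, Ddx3x 0.14). The Y reads and the pooled median are consistent with male knockout and female wild-type donors, so sex may add to any genotype difference in this table. The share of windows with unadjusted p < 0.05 within 10 Mb of Stat4 lay close to that elsewhere (2.94%, 1 of 34, against 2.64%, 133 of 5037; exact Fisher p = 0.599), too few windows to settle whether flanking strain variants play a part. The 1 window was Bzw1, 6.38 Mb from Stat4, and 0 of the others near it passed that p.

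The absence of called differences between Ddx5 knockout and wild type carries limited weight gene by gene, since the self-test recovered 1% of 2-fold and 35% of 4-fold changes of the interaction. These rates may be too low. Unadjusted p < 0.05 was reached by 254 of 7916 windows for the interaction and 347 of 7916 in unstimulated cells. Both are less than the share of 0.05 expected without any effect. For the 3 h IL-12 genes as a set, the ratio of the response in the Ddx5 knockout to that in wild type was 0.902 (0.947 rescaled). With each library of the 15 min or 3 h table left out, and the list redrawn for the latter, it was 0.699 to 1.26, the lowest without the shallow IL-12 knockout replicate 3. It thus stayed above the planned bound of 0.5, but that range is no confidence interval. The knockout libraries with IL-12 scored 1.09 and 1.60 above all windows, the latter in the shallow replicate 3. With 2 libraries per group a loss to 0.5 is therefore not excluded. The same ratio in the Stat4 knockout was 0.0538 (0.231 rescaled), with -0.0151 to 0.786 over left-out libraries, the highest for the list redrawn without IL-12 replicate 1 of the 3 h table, whose genes lay only 0.12 above all windows in wild type. Pol II at the Ddx5 start does not test the knockout, because the part of the gene removed was not given in the sources used here.

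Other splits of the same libraries were counted for the 3 h comparisons, and with 10 splits each they are too few for a share below 0.05. The real split gave 60 calls for IL-18 (highest other 0), 233 for both cytokines (2), 64 for both against IL-12 alone (1) and 37 for both against IL-18 alone (1), each the only 1 of 10 as large. For IL-12 it gave 55, and 2 of 10 splits were as large, the highest 1747 with IL-12 replicate 1 beside unstimulated replicates 2 and 3. That split put libraries with deposited totals of 365886, 418774 and 363677 against those with 533903, 648755 and 478577. With libraries rescaled the real split gave 300 and the highest other 0, so the 1747 calls followed library totals. For the departure from additivity the real count was 0, so 100 of 100 drawn splits reach it by construction and the comparison says nothing; the highest other was 1021.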
